A study of Mus musculus with 2 samples.

How the data were processed

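H3K9ac ChIP-seq had been carried out on hindbrain pooled from newborn mice of both sexes, in 2 biological replicates of 1 group, postnatal day 0, per the labels. The labels name separate biological replicates, and the replicate numbers come from them. The samples analysed here held a single tissue and age and no treatment, so no test between groups was possible.

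The authors deposited 4 lists of peaks in mm10 coordinates, in the narrowPeak layout: a list for each replicate, a list called on both replicates' alignments together, and a replicated list derived from the other lists. Per the deposited descriptions, each list was called from ChIP alignments together with a control alignment. The peak caller, its version, its threshold and the rule that makes a pooled peak a replicated one are not given in the sources used here. Each peak carries a display score of at most 1000 in the deposited lists, which was not analysed here. The enrichment of a peak is a ratio given by the authors' peak caller. The deposited lists give each peak's −log10 p and −log10 q; the lowest −log10 p lay just over 2 in each list, so the lists hold peaks of weak support. The summit of each peak is given in the deposited lists as a distance in bp from the peak's start. Because a list holds only what passed the caller's threshold, a gene without a peak was not called at that threshold and may still carry signal under it. Read depth is unknown, since the files hold peaks and no read counts, and a difference in depth between the replicates would change the number and width of peaks called. The enrichment is that of each list's own call and was used to describe and rank peaks within a list, and between the replicates' lists only in their correlation, in the ratios set beside peak widths and in the rank of the Xist peak.

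All computation was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Genes and TSSs came from the GENCODE M21 annotation of the same assembly (GRCm38, mm10). They comprised 21938 protein-coding genes with 93513 distinct TSSs on the nuclear chromosomes, and 13 mitochondrial genes were left out. Peaks on unplaced scaffolds stayed in the comparison of replicates and out of the analysis of genes. Coordinates are printed starting from 1.

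A peak counted as shared when at least 50% of its length was covered by the other replicate's peaks, and chance was set by 100 random placements of the other list on the same chromosomes. A pooled peak counted as overlapping a replicate's own peak when the overlap covered at least 50% of either peak. For correlations, peaks of the replicates were paired where each was the other's partner of largest overlap in bases. A gene was marked when a replicated peak overlapped the 1 kb either side of any of its TSSs, and its enrichment was the highest of such peaks. Replicated peaks separated by at most 1 kb were joined into domains, a gene's domain was the widest at any of its TSSs, and the widest 5% of domains at protein-coding TSSs were called wide. The summit analysis used genes whose TSSs all lay within 100 bp of each other.

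The 28 gene lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. Of the listed symbols only Ahsp had no protein-coding record in the annotation. Each list was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 28 lists and a threshold of 0.05. Wide domains were compared likewise among marked genes. As promoters rich in CpG are more often marked, each list was also set against 10000 random lists of the same size, matched in 10 bins on the observed to expected CpG ratio within 500 bp of the gene's 5′ end; the smallest p-value these can give before adjustment is 0.0002. The median CpG ratio was 0.713 at marked and 0.177 at unmarked genes. From each list the named genes were the 2 marked members with the highest enrichment (up to 4 where fewer members were marked than unmarked) and up to 3 unmarked members in alphabetical order. Hox genes, the 10 genes with the widest domains, the 10 highest enrichments and the 5 strongest peaks over 5 kb from a TSS were also named by that rule. Shares of peaks and genes are given with 95% Wilson intervals, which cover counting error only.

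The code was tested on simulated data. A simulation of 21938 genes had 3 lists marked in full, 3 lists marked at 5% and the other genes at 64%, and 3 further lists with wide domains. It called 2 of the 3 full lists, and the other had 10 genes and an adjusted p of 0.102. A list of 10 genes was therefore too short to be called higher in the simulation. The 3 lists at 5% were all called lower. With marks drawn at random, 5 of 200 rounds called any list. For wide domains, 3 of 3 lists simulated wide were called and 0 of 25 others. A simulated share of 80% of summits downstream was recovered as 76.8% (the cause was not determined), a shared fraction of 57.6% as 57.6%, and a correlation of 0.9 as 0.897.

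The alternatives were other overlap rules, a −log10 q of at least 5, the 10000 strongest peaks, TSS windows of 500 bp and 2.5 kb, a single TSS per gene, the pooled list, each replicate's own list alone, gaps of 0 and 2 kb, the widest 10% of domains and the CpG-matched lists. Leaving out genes that share a promoter region, counting each domain once and comparing marked genes alone were added after seeing the data.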

Results

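Histone H3 acetylated at lysine 9 (H3K9ac), a modification that marks nucleosomes at active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in the hindbrain of mice on postnatal day 0. The hindbrain gives rise to the cerebellum, pons and medulla, and at birth it holds dividing cerebellar granule cell precursors beside neurons that have already left the cell cycle. The tissue was pooled from males and females. The samples formed 1 group with 2 biological replicates, so the comparisons are between the replicates, between places in the genome and between groups of genes. Replicate 1 was made from 15 mice, and the number behind replicate 2 is not given in the labels. The deposited lists held 54874 peaks for replicate 1, covering 28.2 Mb, and 52247 peaks for replicate 2, covering 39.8 Mb. A list called on both replicates together held 63560 peaks, and the replicated list, a subset of it, held 29119. The files hold peaks and no read counts, so the depth of each library is unknown.

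Both replicates carried H3K9ac at nearly the same set of promoters. Replicate 1's own peaks lay within 1 kb of an annotated transcription start site (TSS) of 14111 of 21938 protein-coding genes (64.3%), those of replicate 2 did so at 14483 genes (66.0%), and 13875 genes were shared. The strongest protein-coding promoter of the replicated list, that of the splicing factor gene Rbm39, had an enrichment of 33.8 in replicate 1 and 43.9 in replicate 2. Actb, which encodes cytoplasmic actin, stood at 31.1 and 28.6, and Ep300, which encodes an acetyltransferase of histones, at 28.03 and 39.3. A peak over a promoter in 1 replicate's list alone was found at 236 genes for replicate 1 and at 608 genes for replicate 2. Enrichment is the authors' value per peak and is used here to describe and rank peaks within a list.

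Peak by peak, the overlap was lower than by gene. Of replicate 1's peaks, 57.9% (95% Wilson interval 57.5 to 58.3, n = 54874) had at least 50% of their length covered by peaks of replicate 2, and 37.2% (36.8 to 37.6, n = 52247) of replicate 2's peaks were covered likewise by replicate 1. Random placement of the other list on the same chromosomes gave 1.53% and 0.968% on average over 100 placements. Sharing rose with enrichment. In the lowest 10% of each list by enrichment 25.8% of replicate 1's peaks and 7.71% of replicate 2's were shared, and in the highest 10% the shares were 100% and 99.4%. These intervals cover counting error only. Among peaks with a −log10 q of at least 5 in both lists, the shares were 95.1% and 66.1%, and where 50% of both peaks had to overlap, the share of replicate 1 was 29.5%. The 66.1% depends on that rule. Of replicate 2's peaks past this threshold on the assembled chromosomes, 18226 had some overlap with a peak of replicate 1's full list and 1346 had none.

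**Figure D1:**
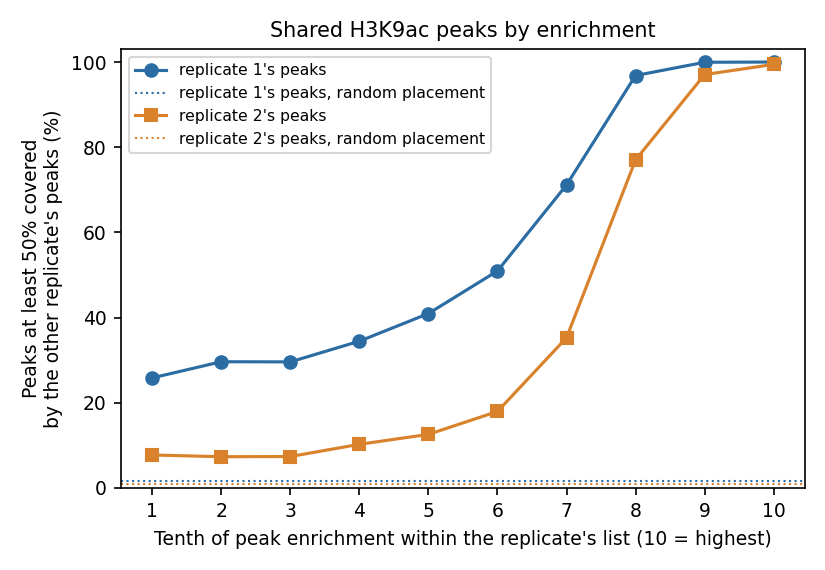
Percent of each replicate's peaks that were at least 50% covered by the other replicate's peaks (vertical axis), in 10 equal groups by enrichment within the replicate's own list (horizontal axis, 10 the highest). Dotted lines give the mean over 100 random placements, 1.53% and 0.968%; sharing reached 100% for replicate 1 and 99.4% for replicate 2 in the highest group.

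Among peaks matched between the replicates, strength was similar in order. Peaks without any overlap in the other replicate's list, 37.8% of replicate 1's and 51.3% of replicate 2's, did not enter. Over 24744 pairs of matched peaks, Spearman's rho of enrichment was 0.898 (95% interval 0.895 to 0.900, counting peaks only) and Pearson's r on the log2 scale was 0.918. These are correlations across peaks, which are not replicates, so no p-value is given. The nuclear factor gene Nfib, which acts in cerebellar granule neuron differentiation, had 16.5 in replicate 1 and 27.3 in replicate 2. Mapt, which encodes the microtubule protein tau, had 19.1 and 22.2. The peak of replicate 2 was the wider member in 89.9% of pairs, with median widths of 625 bp in replicate 1 and 1016 bp in replicate 2.

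The replicated list kept the strong part of the pooled list. All 29119 of its peaks were found in the pooled list word for word, which is 45.8% of it (45.4 to 46.2). The kept peaks had a median enrichment of 5.40 and a median width of 859 bp, and the peaks that were left out had 2.73 and 244 bp. Of pooled peaks with a −log10 q of at least 5, 97.6% were kept. All 24709 pooled peaks that overlapped a peak of each replicate by at least 50% of either peak's length were kept. A further 4410 replicated peaks (15.1%) lacked such an overlap in both replicates' own lists. Of these, 2946 had it in replicate 2 only, 1270 in replicate 1 only and 194 in neither. They were weaker than the other replicated peaks, with a median enrichment of 3.27 against 6.86 and a median −log10 q of 3.77, and 1000 of them lay at a protein-coding TSS.

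H3K9ac was concentrated at promoters. Of the 29113 replicated peaks on the assembled chromosomes, 16989 (58.4%, Wilson interval 57.8 to 58.9) overlapped a window of 1 kb either side of a protein-coding TSS, where 100 random placements gave 5.85% on average and at most 6.20%. These peaks were also the strongest and widest, with a median enrichment of 9.95 and a median width of 1352 bp. Another 4.61% lay only at the TSS of other kinds of genes, 5.503% in exons elsewhere, 19.5% in introns and 12.01% between genes, where random placement gave 33.1% for introns and 49.7% between genes. Peaks over 5 kb from any TSS made up 21.4% (20.9 to 21.9), with a median enrichment of 3.56, and 74.4% of random placements fell there. The promoter share was lower in replicate 1's own list (44.2%), in replicate 2's own list (39.0%) and in the pooled list (34.8%).

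The strongest peaks far from genes' starts were found in both replicates. The highest, with an enrichment of 27.2, covered chromosome 15 from 85668668 to 85675008 in an intron of the long noncoding gene Lncppara, 63.3 kb from the TSS of Ppara, which encodes a nuclear receptor of fatty acid metabolism. The next lay between genes on chromosome 7 from 73616424 to 73619488, 76.3 kb from Chd2, a chromatin remodeller gene, with 21.9. Another, with 21.8, lay on chromosome 17 from 88255578 to 88257547 in an intron of AC165153.1, 184.4 kb from Foxn2. The remaining peaks of the 5 highest lay between genes, at 21.6 on chromosome 18 from 23309417 to 23311325 (nearest gene Dtna) and at 21.4 on chromosome 15 from 96709168 to 96710666 (nearest gene Slc38a2). Coordinates here are mm10 and start from 1.

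In the replicated list, 14023 of 21938 protein-coding genes (63.9%, 63.3 to 64.6) had a peak within 1 kb of a TSS, and these are called marked. The 10 highest enrichments were at Rbm39 (43.8), Wtap (40.2), Tnpo1 (39.1), Actb (39.0), Ywhaz (38.2), Sp3 (38.2), Srsf6 (38.0), Ep300 (38.0), Kmt5b (37.9) and Rbm33 (37.8). Rbm39 and Srsf6 encode splicing factors, Wtap a subunit of the RNA m6A methyltransferase, Tnpo1 a nuclear import receptor, Ywhaz a 14-3-3 adaptor, Sp3 a transcription factor of GC-rich promoters and Kmt5b a histone H4 methyltransferase. Of marked genes, 98.4% had a peak of their own in both replicates' lists. Their median enrichment was 12.6 (quartiles 8.24 and 17.4). For 23.1% of marked genes another protein-coding gene had a TSS within 2 kb, so a peak there cannot be assigned to a single gene.

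Nearly all genes of the pan-neuronal, inhibitory, glutamatergic, granule lineage and progenitor lists had H3K9ac at a TSS. Each of 28 gene lists was compared with all other protein-coding genes by Fisher's exact test, two-sided, and each p-value beside a list is adjusted over the 28 lists. All 20 pan-neuronal genes were marked (exact p = 4.41e-04), with the highest enrichment at Nsg1, an endosomal protein of neurons (23.1 in the replicated list; 18.7 in replicate 1 and 21.6 in replicate 2), and at Mapt (21.3; 19.1 and 22.2). All 20 genes of inhibitory transmission were marked (exact p = 4.41e-04), led by Gabbr1 (26.2; 20.8 and 26.5), a GABA-B receptor subunit, and Gphn (21.1; 14.9 and 21.7), the scaffold of inhibitory synapses. Glutamatergic transmission had 19 of 20 marked (exact p = 3.36e-03), led by the glutaminase gene Gls (21.9; 12.6 and 25.4) and the postsynaptic scaffold gene Shank1 (20.5; 12.6 and 23.0), and its unmarked member was Slc17a8, the vesicular transporter VGLUT3. The granule lineage had 22 of 23 marked (exact p = 1.26e-03), led by Nfib (27.6; 16.5 and 27.3) and Zic1 (23.3; 15.0 and 26.2). Its unmarked member was Gabra6, the GABA-A receptor subunit of mature granule cells. All 18 genes of neural progenitors and proliferation were marked (exact p = 7.40e-04), led by Msi1 (25.6; 12.03 and 29.4), an RNA-binding protein of neural stem cells, and Birc5 (14.9; 14.9 and 16.3), a mitotic regulator. Genes are not replicates, so these p-values set a list against other genes in these libraries and measure no spread between animals.

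Genes used by most cells and genes that respond to signals were also marked more often than all other genes. All 20 housekeeping genes (exact p = 4.41e-04) were marked, led by Actb (39.0; 31.1 and 28.6) and Ywhaz (38.2; 25.3 and 42.0). So were all 20 immediate early genes (exact p = 4.41e-04), led by Dusp1 (19.8; 15.7 and 19.8) and Btg2 (18.2; 13.7 and 18.5), and all 22 genes of histone acetylation enzymes (exact p = 2.36e-04), led by Ep300 and Kat6a (25.6; 20.9 and 19.3). Ribosomal protein genes were marked at 80 of 83 (exact p = 1.41e-11), with Rpl17 (31.7; 22.5 and 31.1) and Rpl13a (28.7; 21.9 and 29.9) highest. The 3 unmarked, Rpl10l, Rpl39l and Rpl3l, are paralogs known for expression restricted to testis or muscle. Histone genes taken by symbol were marked at 55 of 68 (exact p = 5.18e-03), led by Hist3h2a (19.1; 13.6 and 17.3) and by H1f0 (25.6; 17.6 and 26.2), a replacement linker histone that the symbol rule also takes in; Hist1h1d, Hist1h1t and Hist1h2aa were unmarked.

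Of these 10 higher lists, 4 were not called higher against random lists matched on promoter CpG content. The adjusted permutation p-value was 0.0511 for progenitors, 0.109 for immediate early genes and 0.0827 for ribosomal proteins, the highest over each list's alternatives, and the histone list was 15.1 percentage points lower than its matched lists. With a single TSS per gene the acetylation enzymes were no longer called (adjusted exact p = 0.0672, the highest over their alternatives).

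Forebrain regulators and genes of several other tissues were marked less often than all other genes. Of 20 forebrain regulators 4 were marked (adjusted exact p = 2.36e-04): Satb2 (7.03; 5.47 in replicate 1 and 7.75 in replicate 2), a factor of cortical projection neurons, Dlx5 (4.91), Emx1 (4.54) and Lhx2 (3.35; 4.68 and 4.35). Dlx5 and Emx1 had a promoter peak in replicate 1's own list (6.49 and 5.13) and none in replicate 2's. Arx, Dlx1 and Dlx2, which specify forebrain interneurons, had no replicated peak. Microglial genes were marked at 4 of 18 (exact p = 1.26e-03), namely Hexb (7.28; 6.92 and 8.37), Irf8 (6.72; 7.29 and 5.62), C1qa (3.27) and C1qc (2.55), and Aif1, C1qb and Csf1r were not. Erythroid genes were marked at 4 of 14 (exact p = 0.0135), with Klf1 (6.03; 7.22 and 5.93), a red cell transcription factor, and the glycophorin gene Gypa (4.46; 3.65 and 4.04) highest, Tal1 (3.92) and Epor (3.82) below them, and Alas2, Epb42 and Gata1 unmarked. Hepatocyte genes were marked at 3 of 20 (exact p = 3.86e-05). Of these Trf (4.46; 4.39 and 4.17), the transferrin gene, and Afp (3.77; 2.60 and 3.68), the alpha-fetoprotein gene, had peaks in both replicates. The Afp peak lay near the downstream end of the gene, with a −log10 q of 1.15 in replicate 1. The peak counted for Apoa1 (7.38) ran past the downstream end of the gene and reached its window in neither replicate's own list. Ahsg, Alb and Apoa2 were unmarked.

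Heart and skeletal muscle genes were marked at 7 of 20 (adjusted exact p = 0.0135), led by Ckm (7.81; 5.64 and 6.41), the muscle creatine kinase, and the calcium channel gene Ryr1 (5.27; 4.44 and 5.25), with Myl2 (4.84) and Tnni3 (4.29) next, and Acta1, Actc1 and Mb were unmarked. Pluripotency and germline genes were marked at 2 of 18 (exact p = 2.55e-05), the germ cell gene Dazl (8.34; 5.22 and 9.24) and Esrrb (4.81; 4.12 and 4.75), and Acrv1, Ddx4 and Dppa3 were among the unmarked. Keratins were marked at 5 of 49 (exact p = 6.26e-14), led by the epidermal keratins Krt1 (11.4; 10.1 and 10.2) and Krt10 (9.80), with Krt222 (7.52) and Krt87 (7.45) next and Krt12, Krt13 and Krt14 unmarked. Of 1135 olfactory receptor genes Olfr94 alone (9.63; 7.96 and 9.89) was marked, with a p-value too small to be represented, and of 329 vomeronasal receptor genes Vmn1r4 alone (13.7; 10.2 and 14.7; exact p = 2.18e-144). Posterior Hox genes, described with their clusters, were lower too (2 of 24, exact p = 1.19e-07). Any annotated TSS could mark a gene, and some of these peaks lay away from the gene's 5′ end. Those of Krt1 and Olfr94 lay near the downstream end of the gene. With a single TSS per gene, 2 of 49 keratins, 0 of 1135 olfactory receptors, 1 of 20 hepatocyte genes and 4 of 20 muscle genes were marked. Trf, Ckm and Vmn1r4 had another gene's TSS within 2 kb. Without genes that share a promoter region, 0 of 326 vomeronasal receptors were marked.

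Of these 10 lower lists, 4 were not called lower against CpG-matched random lists. The adjusted permutation p-value was 0.357 for microglia, 0.423 for hepatocytes and 0.983 for muscle, the highest over each list's alternatives, and the erythroid list lay 0.951 points above its matched lists. The forebrain call ended with the pooled list (-11.7 points, adjusted exact p = 0.383, the highest over its alternatives), the microglial call with replicate 2's own list, where 8 of 18 genes were marked (adjusted exact p = 0.0992), and the muscle call with a window of 2.5 kb (adjusted exact p = 0.212).

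**Figure D2:**
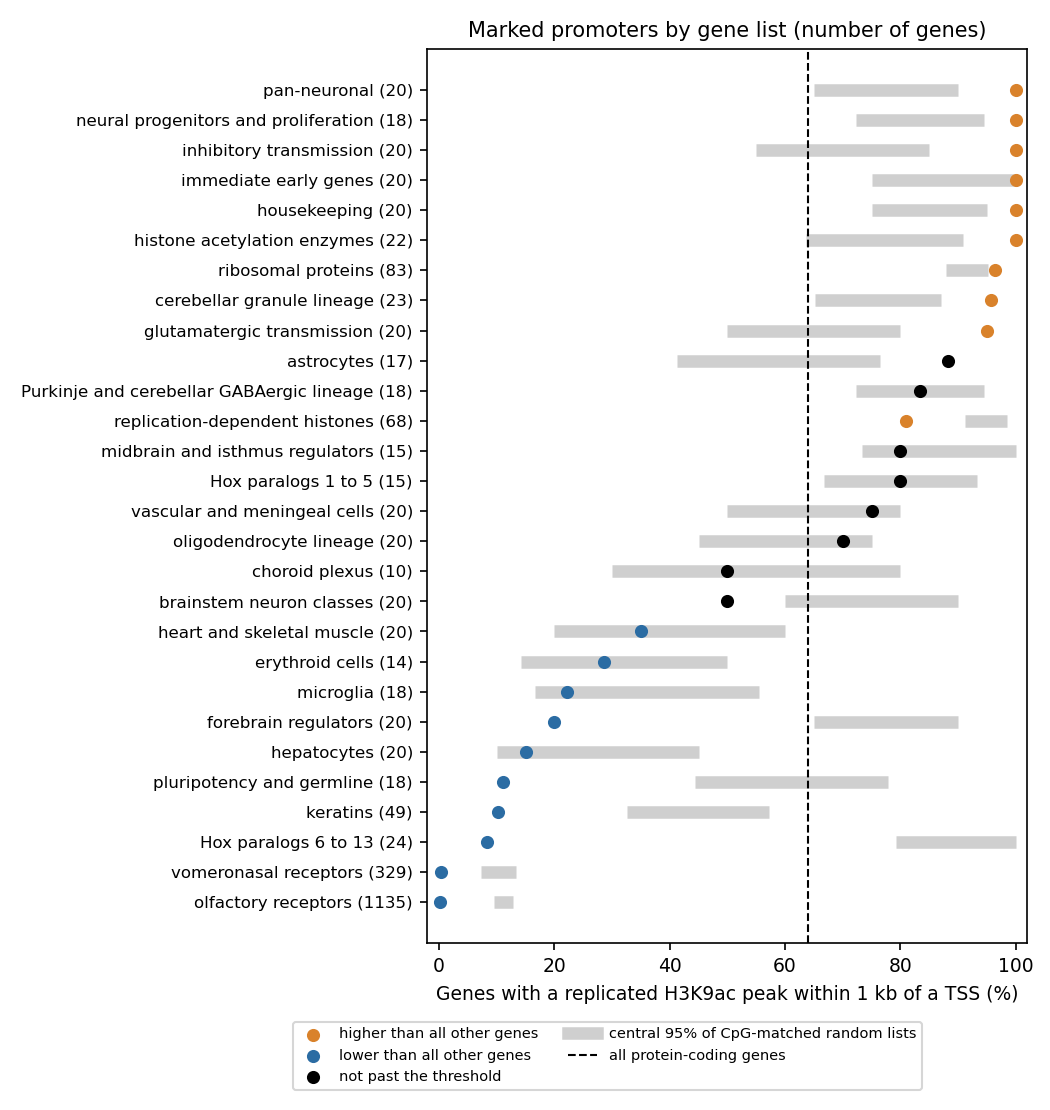
Percent of each list's genes marked by a replicated peak within 1 kb of a TSS (points; number of genes in brackets). Orange and blue points passed the adjusted threshold of 0.05 above or below all other genes, grey bars span the central 95% of 10000 random lists of the same size matched on promoter CpG ratio, and the dashed line is the 63.9% of all protein-coding genes; olfactory and vomeronasal receptors lie near 0, and pan-neuronal and inhibitory genes at 100%.

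The remaining 8 lists did not pass the test against all other genes. Astrocyte genes were marked at 15 of 17 (adjusted exact p = 0.0562), led by Slc1a2 (16.2; 12.6 and 16.0), the glutamate transporter GLT-1, and the glutamine synthetase gene Glul (11.4; 10.4 and 17.3), with Agt and S100b unmarked. Over the alternatives this list's adjusted p-value ran from 0.01, against CpG-matched lists, to 0.540. Purkinje and cerebellar GABAergic genes were marked at 15 of 18 (exact p = 0.175), led by Grid2 (17.3; 14.0 and 20.1), a glutamate receptor of Purkinje cells, and Ebf3 (16.4; 12.3 and 16.6), and Pcp2, Ptf1a and Skor2 were unmarked. They were called higher with the pooled list (exact p = 1.54e-03, the lowest over the alternatives) and with replicate 1's own list (exact p = 8.32e-03), and the highest adjusted p-value was 1. Midbrain and isthmus regulators stood at 12 of 15 (exact p = 0.317), led by En2 (13.1; 6.70 and 15.8) and by Gbx2 (6.18; 5.91 and 5.35), which is known for placing the midbrain and hindbrain border. Foxa1, Foxa2 and Wnt1 were unmarked. Brainstem neuron classes stood at 10 of 20 (exact p = 0.297), led by Mafb (8.54; 6.49 and 9.36) and Tlx3 (6.91; 4.97 and 8.29), with the noradrenergic gene Dbh, the serotonergic regulator Fev and Gata3 unmarked. Over their alternatives the adjusted p-value ran from 8.20e-03, against CpG-matched lists and lower, to 1.

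Oligodendrocyte lineage genes stood at 14 of 20 (adjusted exact p = 0.648), led by Mbp (15.4; 11.3 and 16.0) and Sirt2 (11.2; 8.78 and 10.7). The Mbp peak lay at the upstream end of the annotated gene, and whether it serves the transcripts used in myelin was not tested. Sirt2 had another gene's TSS within 2 kb. The myelin genes Ermn, Mag and Mobp were unmarked. Vascular and meningeal genes stood at 15 of 20 (exact p = 0.386), led by the endothelial receptor gene Kdr (8.57; 6.42 and 9.75) and Foxc1 (6.54; 3.40 and 6.68), with Col1a1, Dcn and Rgs5 unmarked. Choroid plexus genes stood at 5 of 10 (exact p = 0.530), led by Clic6 (6.00; 4.79 and 7.49) and Kl (5.45; 4.10 and 5.25), with Aqp1, Folr1 and Kcne2 unmarked. Anterior Hox genes stood at 12 of 15 (exact p = 0.317) and were called higher with the pooled list (exact p = 0.0356, the lowest over the alternatives) and with replicate 2's own list (exact p = 0.0379), with a highest adjusted p-value of 1.

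Hox genes, which pattern the body axis by paralog number, were marked at the anterior end of their clusters. Of paralogs 1 to 5, which are used in the hindbrain and neck, 12 of 15 were marked, and of paralogs 6 to 13, used further back, 2 of 24. The difference was 71.7 percentage points (Fisher's exact test, two-sided, p = 8.49e-06). Neighbouring genes of a cluster can share peaks and domains, so they are not independent. The p-values of the Hox lists count each gene as independent and are therefore too small. The marked anterior genes were Hoxa1, Hoxa2, Hoxa4, Hoxa5, Hoxb2, Hoxb3, Hoxb4, Hoxb5, Hoxc4, Hoxc5, Hoxd3 and Hoxd4, with the highest enrichment at Hoxb2 (13.4; 10.5 in replicate 1 and 8.97 in replicate 2) and Hoxa1 (11.6; 9.004 and 12.4). Hoxa3, Hoxb1 and Hoxd1 had no replicated peak at a TSS. The marked posterior genes were Hoxa7 (5.83) and Hoxb6 (4.98), with domains of 0.320 kb and 0.587 kb. Replicate 1's own list marked 12 of 15 and 3 of 24, and that of replicate 2 marked 14 of 15 and 3 of 24.

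With gaps of up to 1 kb joined, the widest TSS domain of the genome was in the Hoxa cluster. It ran on chromosome 6 from 52158293 to 52180603, 22.3 kb, from the TSS of Hoxa1 past that of Hoxa2 and into the annotated span of Hoxa3, all of whose TSSs lay outside it. The domain also covered the TSS of 5730596B20Rik. Its widest single peak, at Hoxa2, was 6810 bp wide, less than the 12531 bp of the peak at Zic2. Hoxb3 had a domain of 12.1 kb.

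**Figure D3:**
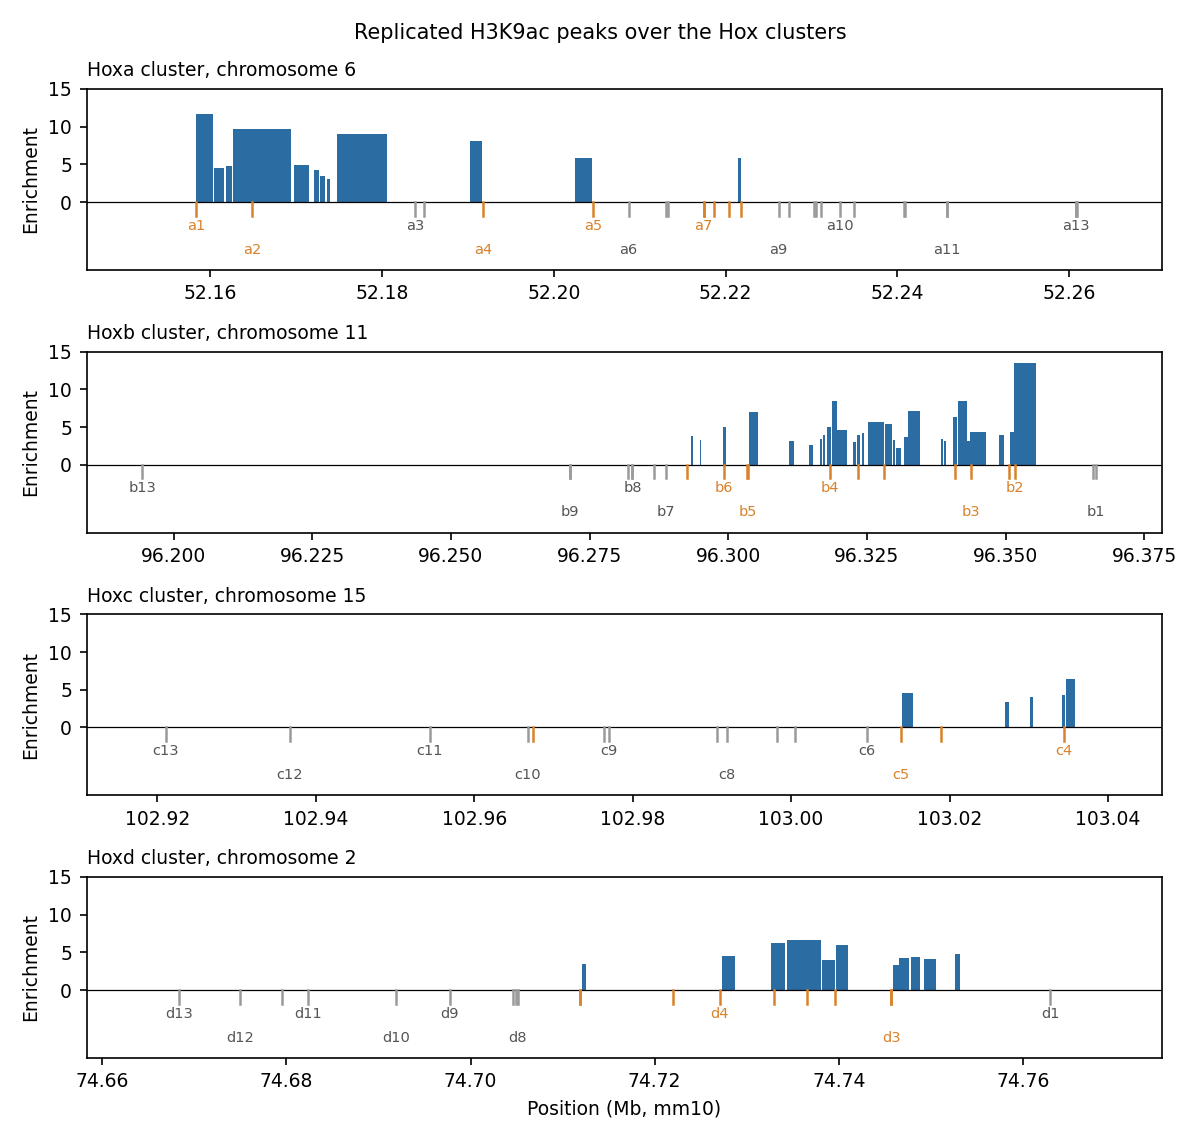
Replicated peaks over the 4 Hox clusters in mm10 coordinates (horizontal axis, Mb), with bar height the enrichment in the replicated list and bar width the peak. Ticks are annotated TSSs, orange for marked genes and grey for unmarked genes, and each gene's name stands at its most downstream TSS. Of paralogs 1 to 5, 12 of 15 were marked, and of paralogs 6 to 13, 2 of 24.

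Wide acetylated domains were more frequent at genes of the cerebellar granule and Purkinje lineages, pan-neuronal genes and anterior Hox genes than at other marked genes, while brainstem neuron classes did not pass the test. Joined over gaps of up to 1 kb, the 14207 domains at a protein-coding TSS had a median width of 1731 bp (quartiles 1138 and 2456), and the widest 5%, of at least 4249 bp, covered the TSSs of 814 marked genes (5.80%). After the Hoxa domain, the widest lay at Nfib (20.7 kb), at Zic2 and Gm10837 (20.6 kb), Bahcc1 (19.4 kb), Mn1 (18.7 kb) and the shared promoter region of Zic1 and Zic4 (17.9 kb). The Zic genes encode zinc-finger factors of cerebellar progenitors. A gene's domain could lie at any of its TSSs, so genes with more TSSs had more chances of a wide domain. That of Nfib lay away from the gene's 5′ end. Of the marked granule lineage genes 13 of 22 had a wide domain (adjusted exact p = 6.62e-10): Nfib, Zic1 to Zic5, Pax6, Meis1, Nfia, Barhl1, Mycn, Cbln1 and Neurod1. The same held for 9 of 20 pan-neuronal genes (exact p = 9.43e-06), among them Tubb3, Map2 and Rbfox3, for 6 of 15 Purkinje and cerebellar GABAergic genes (exact p = 6.69e-04), Lhx5, Ebf3, Lhx1, Ebf1, Grid2 and Foxp2, and for 6 of 12 anterior Hox genes (exact p = 2.39e-04). Hoxa1 and Hoxa2 share a domain, and with each domain counted once the anterior Hox count was 5 of 11 (adjusted exact p = 1.04e-03). Progenitor genes had 7 of 18 (exact p = 2.74e-04), among them Sox2 and Hes5, and immediate early genes 5 of 20 (exact p = 0.0227), Ier2, Nr4a3, Jun, Junb and Egr1. Members in this paragraph outside the rule for named genes were chosen after their values were seen. Brainstem neuron classes had 1 of 10, Tlx3 (adjusted exact p = 0.970), midbrain and isthmus regulators 3 of 12, Pax2, En2 and Otx2 (adjusted exact p = 0.101), housekeeping genes 1 of 20, Polr2a, acetylation enzymes 0 of 22, ribosomal protein genes 1 of 80, Rps19, and forebrain regulators 0 of 4, and none of these lists passed the test.

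The gap that was joined decided some of these calls. With no gap joined, the difference from the other marked genes was -1.11 points for progenitors (adjusted exact p = 1) and -1.66 points for immediate early genes (adjusted exact p = 1), and the anterior Hox call ended (18.4 points higher, adjusted exact p = 0.165); these are the highest adjusted p-values over the alternatives of each list. Both the immediate early call (8.89 points, adjusted exact p = 0.337) and the progenitor call (16.1 points, adjusted exact p = 0.0751) also ended when gaps of up to 2 kb were joined, so of the gaps tried they held at 1 kb alone. The immediate early call ended with replicate 2's own list too (13.7 points, adjusted exact p = 0.105) and the progenitor call with replicate 1's (16.2 points, adjusted exact p = 0.0962). Other lists were called only under alternatives. With no gap joined these were astrocytes (33.4 points, adjusted exact p = 0.00238), glutamatergic genes (19.7 points, 0.0385) and inhibitory genes (18.4 points, 0.0405). With 2 kb joined they were inhibitory genes (23.9 points, adjusted exact p = 0.00893), midbrain and isthmus regulators (27.2 points, 0.0244) and histones (10.3 points, 0.0244). With replicate 2's own list they were midbrain and isthmus regulators (24.5 points, adjusted exact p = 0.0328) and oligodendrocyte genes (22.3 points, 0.0374), with a −log10 q of at least 5 inhibitory genes (20.7 points, 0.0154), and in the widest 10% glutamatergic genes (25.2 points, 0.0165). The highest adjusted p-value over the alternatives was 1 for astrocytes, midbrain regulators, oligodendrocyte genes and histones, 0.670 for glutamatergic and 0.105 for inhibitory genes.

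Granule lineage genes and forebrain regulators differed in wide domains. In the widest 5% were 13 of 23 granule lineage genes and 0 of 20 forebrain regulators, a difference of 56.5 percentage points (Fisher's exact test, two-sided, p = 3.34e-05). Most forebrain regulators had no domain at all, and among marked genes alone, an alternative chosen after seeing the data, the counts were 13 of 22 and 0 of 4. With 4 forebrain genes and these totals no outcome could pass the threshold (the lowest exact p = 0.0957), so this says nothing on whether marked genes differ.

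Within promoters, H3K9ac summits lay on the transcribed side. Of 2712 marked genes with a single annotated promoter, 2222 (81.9%, Wilson interval 80.4 to 83.3) had the summit of their strongest peak downstream of the TSS (exact binomial test against 50%, two-sided, p = 5.43e-262). The test and the interval count each gene as independent and measure no spread between animals. In the simulation a downstream share of 80% was recovered as 76.8%, an error that the interval does not cover. The median position was 220 bp downstream, with quartiles at 107 and 320 bp. The share was 80.1% in replicate 1's own list and 81.2% in that of replicate 2.

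**Figure D4:**
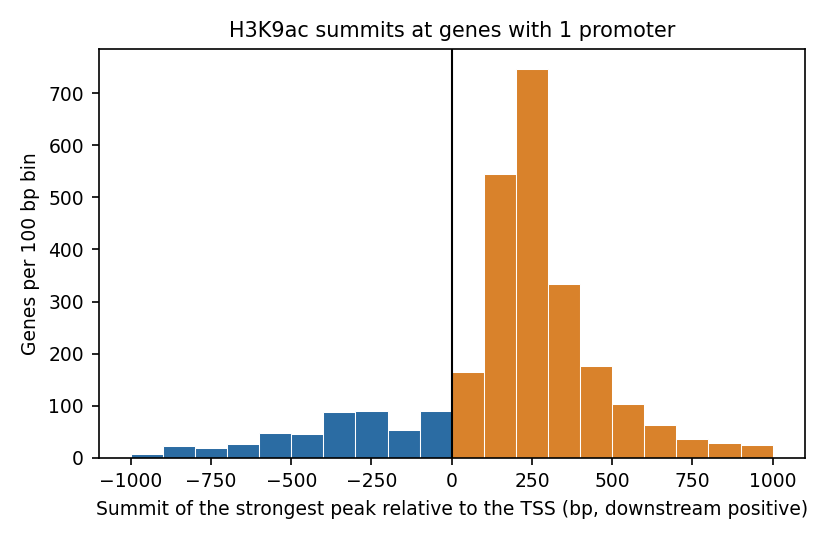
Number of genes with a single promoter (vertical axis, per 100 bp bin) by the distance of the strongest peak's summit from the TSS (horizontal axis, bp, downstream positive). Orange bars lie downstream and blue bars upstream; 2222 of 2712 summits were downstream, and the fullest bin, 200 to 300 bp, held 747 genes.

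Genes on the X chromosome were marked less often than autosomal genes. On X 442 of 948 protein-coding genes were marked (46.6%), and on the autosomes 13578 of 20807 (65.3%). The difference was -18.6 percentage points (Fisher's exact test, two-sided, p = 2.70e-30), and it was -20.2 and -19.4 points in replicate 1's and replicate 2's own lists. Marked X-linked genes had a median enrichment of 7.996, and marked autosomal genes 12.9. Neither promoter CpG content nor the number of X copies, which differs between the sexes pooled here, was matched between X and autosomes. Their part in the difference was not tested. A promoter with signal under the caller's threshold counts as unmarked, so the lower share does not show that X promoters lacked H3K9ac. The p-value counts each gene as independent and measures no spread between animals.

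Peaks found in a single replicate were weak, narrow and mostly away from promoters. Without any overlap in the other replicate were 20721 of replicate 1's peaks (37.8%) and 26807 of replicate 2's (51.3%). In replicate 1 these had a median enrichment of 3.22 against 4.68 for shared peaks and a median width of 193 bp against 451 bp. In replicate 2 the medians were 2.97 against 6.72 and 295 bp against 986 bp. At a protein-coding TSS lay 12.3% of the unshared and 63.5% of the shared peaks of replicate 1, and 15.3% and 63.9% in replicate 2. A −log10 q of at least 5 was reached by 252 of the unshared peaks in replicate 1 and by 1346 in replicate 2.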

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

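Both tests of the Y-linked peaks below were chosen only after those peaks had been seen, although their predictions were written before the tested values were. Promoters of long noncoding genes, which were in none of the gene list comparisons, carried replicated peaks: 802 of 7986 such genes with a TSS over 2 kb from any protein-coding TSS were marked (10.04%, Wilson interval 9.40 to 10.7), with a median enrichment of 5.27. The highest, chosen after their values were seen, were 1810026B05Rik (45.4 in the replicated list; 33.2 in replicate 1 and 46.2 in replicate 2), the shared promoter region of C130071C03Rik and Gm26803 (33.4; 21.9 and 35.03) and 2610037D02Rik (31.1; 23.2 and 31.8). The filter was on the distance between TSSs, so a wide peak of a coding gene could mark a noncoding one. Gm11266 was marked by the peak of Nfib (27.6). Gm17753 was marked by that of H1f0 (25.6), with 4.44 in replicate 1 and 4.28 in replicate 2. How many of the 802 shared a coding gene's peak was not counted. Outside the assembled chromosomes, which the gene comparisons did not reach, the replicated list held 6 peaks: 2 on 4_GL456216_random, 1 on Un_JH584304 and 3 on X_GL456233_random.

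On the Y chromosome, which had no comparison of its own, replicate 2's own list held 5 peaks, at Kdm5d (5.62), Uty (7.49), Ddx3y (5.08), Eif2s3y (2.94) and Gm28587 (2.67), while replicate 1's list held 0 and the replicated list 3 (Uty 5.63, Kdm5d 4.18 and Ddx3y 4.00). A lower sensitivity of replicate 1 is argued against, since 96.5% (Wilson interval 95.6 to 97.2) of 2117 autosomal promoter peaks of replicate 2 with a −log10 q between 7.59 and 15.9, the range of the 3 strongest Y-linked peaks, overlapped a peak of replicate 1. Xist, which is transcribed from the inactive X of females, ranked 18.2 percentile points higher in replicate 1 (35.1 against 16.9). That difference passed the level set beforehand as a sign of a lower share of male tissue in replicate 1's pool. However, 5.30% of 1339 autosomal genes of similar rank differed by at least as much in that direction. A lower share of male tissue could therefore not be told apart from promoter-to-promoter variation. The number of males and females in each pool is not in the labels used here, so the composition of the pools stays open. The design has no groups that differ in sex, and no other biological explanation was tested.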

How the results depend on the processing

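The comparison restricted to marked genes, the lists without shared promoter regions and the domains counted once were chosen only after the data were seen. The share of peaks found in the other replicate depended on the rule. For replicate 1 and replicate 2 in turn it was 62.2% and 48.7% with any overlap, 29.5% and 31.0% where both peaks had to be covered by 50%, 95.1% and 66.1% at a −log10 q of at least 5, and 92.35% and 78.4% among the 10000 strongest peaks of each. With at least 50% of the peak required, 42.1% and 62.8% of peaks were found in a single replicate. Rho was 0.908 for −log10 p and 0.925 where 50% of both peaks had to overlap. The replicated share of the pooled list was 97.6% at a −log10 q of at least 5, and 39.6% of pooled peaks overlapped both replicates' own lists. The share at promoters was 55.02% with 500 bp, 66.1% with 2.5 kb, 71.3% at a −log10 q of at least 5, 34.8% in the pooled list and between 39.0% and 44.2% with either replicate left out. By construction a stricter threshold keeps the stronger peaks; the cause of the other shifts was not tested.

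Marked forebrain and granule genes alone differed by 59.1 points; with 4 forebrain genes left, no outcome could pass the threshold (exact p = 0.0957 at the lowest). Differences that reversed and passed the threshold as reported or under the alternative were those of erythroid genes (0.951 points) and histones (-15.1 points) against CpG-matched lists, of wide domains with no gap joined for progenitors (-1.11 points) and immediate early genes (-1.66 points), and of wide domains joined over 2 kb for histones (10.3 points); the cause was not tested. Of the other values that answer a comparison, 61 were tests that kept their direction and side of the threshold, or counts that moved by a factor below 1.5. The number of lists called higher was 7 to 13 (10 as reported), lower 8 to 10 (10), and called for wide domains 5 to 7 (6), not always the lists reported. Differences that kept their direction and side of the threshold were those of Hox (67.5 to 80.8 points), X chromosome (-20.2 to -18.02 points) and summits (80.1% to 83.9%). For single lists 411 values stayed on their side of the threshold, 17 passed the threshold newly and 15 no longer did. The newly passing and lost values kept their direction, while some of the 411 changed sign with neither value past the threshold, such as Purkinje genes (-1.44 points) and midbrain regulators (-5.79 points) against CpG-matched lists. The depth of the libraries is unknown, so peaks missing from a list bound no signal, and both replicates come from 1 group. No paired analysis was possible because the samples form a single group.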

Other observations

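The genes in this paragraph were chosen after their values were seen, and the tests of width and CpG content further on before theirs were. Wide domains also lay at genes that were in none of the gene lists, and what these genes share was not tested. Meis2, a cofactor of Hox proteins, had a domain of 16.9 kb (enrichment 10.7 in the replicated list; 9.23 in replicate 1 and 9.32 in replicate 2), and Pou3f3, a POU-domain factor of neural tissue, one of 13.7 kb (18.0; 12.6 and 21.1). Nfix, a relative of Nfib, had 11.2 kb (23.3; 14.0 and 28.6), the orphan nuclear receptor gene Nr2f1 11.1 kb (29.4; 19.5 and 31.8), the homeobox gene Irx5 10.9 kb (15.1; 10.3 and 15.8) and Pax3, a regulator of dorsal neural progenitors, 10.1 kb (9.63; 8.62 and 10.7). Other examples were Kdm6b, a histone demethylase gene, with 14.01 kb (18.2; 4.49 and 17.1), the thyroid hormone receptor gene Thra with 11.6 kb (33.6; 24.9 and 33.96), and a domain of 12.5 kb shared by Kif22, Maz and Prrt2 among others. Each enrichment is that of the highest peak at any TSS of the gene in its own list. The values of a gene, such as the 4.49 of Kdm6b in replicate 1, therefore need not come from the same peak.

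Matched peaks were wider in replicate 2 than in replicate 1 in 89.9% of pairs. A longer read extension alone is argued against, since among peaks with a single partner each the median difference was 283 bp in the widest of 4 equal groups of pairs (95% interval 271 to 293) and 94 bp in the narrowest, while the shortest peaks of the lists differed by 75 bp. Higher enrichment in replicate 2 was weighed by rho between the ratio of widths and the ratio of enrichments. Over all such pairs it was -0.0177, on the side set beforehand as counting against this cause. This pooled rho cannot decide, since the ratios moved in opposite directions between groups. The median width ratio was 1.71 in the second narrowest group and 1.18 in the widest, where the median enrichment ratio was 1.08 and 1.38. Within the 2 narrower groups rho was 0.340 and 0.216, past the level set beforehand as a sign of this cause. In the narrowest, however, the median enrichment ratio of replicate 2 to replicate 1 was 0.956 while the width ratio was 1.45, so a contribution there stays open at most in part. Within the 2 wider groups rho was -0.0479 and -0.0391, although their median enrichment ratios were 1.28 and 1.38. Replicate 2 was the higher in 74.5% of all matched pairs, and higher enrichment stays open over all pairs. Sequencing depth, which the lists do not give, stays open, and no biological explanation was tested.

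Lists of genes differed in the share of marked promoters, and promoters rich in CpG were marked more often (median CpG ratio 0.713 at marked and 0.177 at unmarked genes). Of the 20 called lists, 15 lay outside the central 95% of CpG-matched random lists, the histone list among them on the opposite side. CpG content was matched at the gene's 5′ end alone, while a gene could be marked at any TSS. Ywhaz and Nfib, whose highest peaks lay away from that end, had ratios of 0.127 and 0.236 there. Lists above their matched lists therefore cannot argue against CpG content at the marked TSS. Lists below theirs argue against CpG content as the whole cause, such as posterior Hox genes (8.33% marked against 90.7%) and forebrain regulators (20% against 79.2%). Immediate early, microglial, erythroid, hepatocyte and muscle genes lay inside that range, and progenitors and ribosomal proteins, though outside it, missed the adjusted threshold (permutation p = 0.0511 and 0.0827), so CpG content could account for the difference of these lists from other genes. The adjusted permutation p-value was 0.0007 for inhibitory genes, forebrain regulators and posterior Hox genes, and the value before adjustment, 0.0002, is the smallest that 10000 random lists can give. Expression of the genes was not measured in these libraries and stays open.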
